A study of Homo sapiens with 6 samples.

How the data were processed

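RNA of 6 samples of A431 cells, 2 in each of 3 groups (control, EGF, and EGF plus gefitinib), was measured on 1 array per sample. Per the labels, the cells were grown in medium with 10% serum, starved for 24 h, treated with 100 ng/ml EGF with or without 10 µM gefitinib and harvested after 30 min. One treatment description covers every sample, and the order of the additions is not given in the sources used here. Total RNA was biotin-labelled with the WT PLUS kit of Affymetrix, per the labels. The deposited values are on a log2 scale and were made by the authors with Transcriptome Analysis Console, per the submitters' processing notes. The version of that program and the methods of background correction, summarization and normalization are not given in the sources used here. The log2 scale was read from the values themselves, which ran from 1.58 to 18.9 with near-equal medians and quartiles on all 6 arrays. The values were used as deposited, with no further background correction or normalization. No column of values was left without a sample.

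The value table held 24351 probe sets. Control probe sets were left out of the fit, 2903 in all, of which 612 were negative controls, 2197 positive controls, 63 ERCC spike probe sets, 8 other spike probe sets and 23 background probe sets. The 21448 transcript probe sets that remained were all tested, with no filter on low values. The platform annotation gave 1 gene symbol for 17709 of them, several for 0, and did not list the other 3739, which are unnamed here. All 17709 gene identifiers were found in the gene table used for current symbols, and 0 symbols changed. For 20 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays stood for the gene, which left 17687 genes. No genome coordinates are given, since no genome build was used here.

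For each array, the 95th percentile of the negative-control probe sets (7.14 to 7.65) was taken as the background limit. A probe set at or below it on both arrays of a group has only an upper bound there. Its fold was then computed from the brighter group's mean against the mean, over the dimmer group's arrays, of the background limit, and no fold is given where that came to less than 1 or where both groups lay below the limit. The fitted log2 change of such a probe set is printed as fitted and is not a bound. The depth of an array is not a count, and the number of arrays limits the precision.

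Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with jsonlite 2.0.0 for reading the labels. All 6 arrays entered 1 fit with 3 group means, so that the groups shared an estimate of the spread with 3 residual degrees of freedom and 4.22 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 21448 probe sets, and a probe set was called at an adjusted p under 0.05. Gene lists were tested with limma's camera on 1 probe set per gene with a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the lists. With an estimated correlation, camera takes its p-value from the 3 residual degrees of freedom, so small p-values are hard to reach at any correlation. Such a p-value therefore does not decide whether correlation between genes accounts for a list's call. Of 28 lists 27 had measured members. The list of mitochondrially encoded transcripts and RNA quality had none, so RNA quality was not analysed here. The lists held 537 entries, of which 456 had a probe set. SESN1 stood in both the FOXO and the p53 list. For the count adjusted over the list alone, the p-values of a list's own members were adjusted among themselves.

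The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. In each comparison the rule named up to 12 genes with the largest rise and up to 12 with the largest fall among called probe sets with 1 symbol whose arrays did not overlap between the groups. EGFR, FOS, EGR1 and DUSP6 were always named, as were up to 4 members of each list with the largest absolute moderated statistic. The genes of a list that this rule picked but that were not called are mostly not printed.

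Comparisons that share arrays were set beside 100 simulations of unchanged groups (seed 1) and beside the overlap of independent lists, the product of both counts divided by the 21448 probe sets tested. The share of the EGF change left with gefitinib was measured by choosing 50 probe sets on the arrays of 1 number and measuring them on those of the other, and as a slope through the origin over the immediate early list. That slope was also taken with each change on arrays of a different number, as the mean product of the EGF change on arrays of 1 number and the EGF plus gefitinib change on those of the other, divided by the mean product of the EGF changes on both. Replicate numbers served there only to split the arrays.

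The fit and the list test were tested on simulated data with known answers. Over 10 runs with 200 changed probe sets among 21448, the fit recovered 42.1%, 99.1% and 100% of changes of 2, 4 and 8-fold for EGF against control. It recovered 41.3%, 98.8% and 100% for EGF plus gefitinib against EGF, and 47.5%, 99.3% and 100% for EGF plus gefitinib against control. The share of calls that were false was 6.03%, 6.60% and 5.30%. These shares hold for simulated noise that was independent between probe sets, and do not give the share of false calls in the deposited values. A list of 18 members shifted by 1 log2 unit was called in 10 of 10 runs in each comparison, and 0.385%, 0.385% and 0% of the other lists were called. Because genes varied independently in these runs, they cannot show how often camera wrongly calls lists whose members vary together. In the data the estimated correlation within a list reached 0.566, for the histones.

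The alternatives tried were quantile normalization, centring each array on its median, a replicate block, a fit of the 4 arrays compared, eBayes with an intensity trend or a robust prior, filters at the 25th percentile and the median of the mean value, probe sets with 1 symbol, other thresholds of adjusted p and fold, limma's treat against 1.2-fold, camera on ranks, fry, and leaving out each array in turn. Where leaving out an array left 1 array in a group, that array was assumed to vary like the other groups. Array weights, keeping the control probe sets in the fit, centring for the named genes, separate control arrays for the slope and separate EGF arrays for the overlap of calls were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.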

Results

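Gene expression was measured on 6 arrays of A431 cells, a human epidermoid carcinoma line with a very high level of the epidermal growth factor receptor (EGFR). The cells had been starved for 24 h. Of the 3 groups, the control group was left untreated, the EGF group was given 100 ng/ml of epidermal growth factor, the ligand of EGFR, and the third was given the same dose of EGF with 10 µM gefitinib, an inhibitor of the EGFR kinase. Each group held 2 arrays. The labels give a single harvest, 30 min after treatment, and do not say when gefitinib was added relative to EGF. They call the arrays of a group biological replicates, but nothing says that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value given here.

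The values of 21448 transcript probe sets were compared. On the single arrays, 38.4% to 42.1% of them lay above the limit set by the negative-control probe sets. The median over the transcript probe sets ranged from 6.07 to 6.16 on the log2 scale. Across probe sets, which are not independent replicates, the arrays of a group correlated at 0.991 to 0.994, and the closest arrays of different groups at 0.987. The first principal component held 54.0% of the variance and set the EGF arrays against the EGF plus gefitinib arrays, with the controls between them. The second held 21.6% and separated the controls from both treated groups. The median SD between the arrays of a group was 0.149 for control, 0.148 for EGF and 0.181 for EGF plus gefitinib. Changes below are log2 differences between group means ± the standard error of the limma fit (n = 2 arrays per group). Where the dimmer group lay within the negative-control range on both arrays, the fold is a lower bound and is written "at least", and the log2 difference is the fitted value and does not give the size of the change.

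The first comparison asked what EGF changed in the starved cells. FOSL1, an AP-1 subunit induced by growth factors, rose 16.1-fold, from 9.87 ± 0.11 to 13.88 ± 0.01 (SD, n = 2). DUSP6, a phosphatase that switches off ERK, rose 16.5-fold, from 8.46 ± 0.14 to 12.50 ± 0.12 (SD, n = 2). SOCS2, an inhibitor of cytokine receptor signalling, rose at least 5.48-fold, and IL1RL1, the receptor of interleukin 33, at least 8.97-fold. BCL6, a transcriptional repressor that FOXO factors induce, fell 31.4-fold, from 12.66 ± 0.08 to 7.68 ± 0.21 (SD, n = 2). TXNIP, a thioredoxin inhibitor that limits glucose uptake, fell at least 7.32-fold, and CYP1B1, a cytochrome P450 under the control of the aryl hydrocarbon receptor (AHR), at least 18.5-fold.

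The other large rises were those of CXCL10, a chemokine (5.58 ± 0.34, adjusted p = 0.000421), HAS2, a hyaluronan synthase (4.92 ± 0.18, adjusted p = 0.000126), GJB6, a gap junction protein (4.15 ± 0.17, adjusted p = 0.000128), and IL7R, a cytokine receptor (3.98 ± 0.36, adjusted p = 0.00144). SERPINB3 and SERPINB4 (5.49 ± 0.25 and 5.56 ± 0.24) and SPRR2A and SPRR2D (4.07 ± 0.19 and 4.30 ± 0.27) also rose, but the members of each pair are near-identical paralogs, so the split between them is uncertain. The other large falls were those of PSCA, a cell surface antigen (−5.30 ± 0.42), MPPED2 (−4.86 ± 0.21), BCAS1 (−4.50 ± 0.17), FAXDC2 (−3.96 ± 0.28), SCNN1G, a sodium channel subunit (−3.91 ± 0.25), RIPK4, a kinase of epidermal differentiation (−3.69 ± 0.19), HSD17B11 (−3.61 ± 0.22), ID2, an inhibitor of differentiation (−3.56 ± 0.28), and YPEL3 (−3.56 ± 0.23). Their adjusted p-values ran from 0.000126 for BCAS1 to 0.00109 for ID2. Within the negative-control range in the dimmer group lay CXCL10 (at least 7.99-fold), HAS2 (at least 2.47-fold), IL7R (at least 6.77-fold), SERPINB3 (at least 42.6-fold), SPRR2A and SPRR2D (at least 8.21-fold and 8.41-fold), BCAS1 (at least 20.8-fold), FAXDC2 (at least 8.39-fold), SCNN1G (at least 1.15-fold), HSD17B11 (at least 2.78-fold) and ID2 (at least 3.33-fold), so the order of these changes by size is not known. EGFR itself measured 14.40 ± 0.03 in the control and 14.44 ± 0.00 in the EGF group (SD, n = 2), a difference of 0.04 ± 0.17 (limma, adjusted p = 0.916). EGR1, an early growth response factor, differed by 0.10 ± 0.34 (adjusted p = 0.894). The probe set of FOS lay within the negative-control range in both groups and differed by −0.42 (adjusted p = 0.321).

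**Figure D1:**
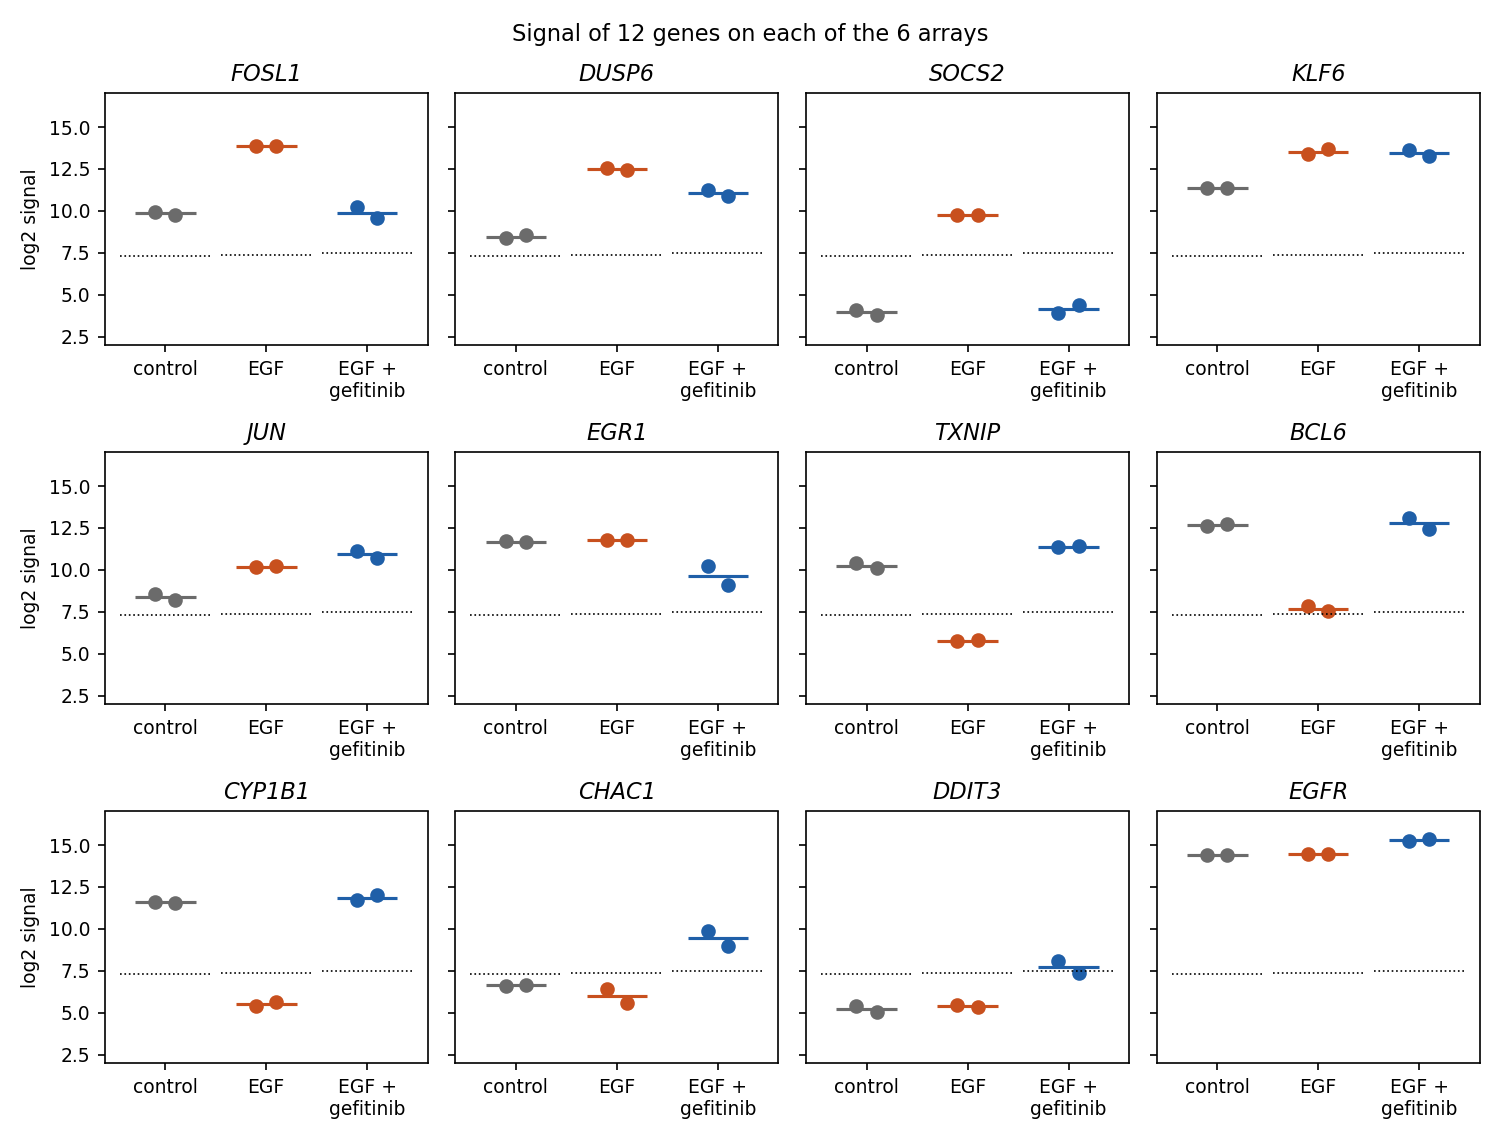
Log2 expression value (vertical axis) of 12 genes in the control, EGF and EGF plus gefitinib groups (horizontal axis), with a point for each array, a line at the group mean of 2 arrays and a dotted line at the mean negative-control limit of the group's arrays. FOSL1 went from 9.87 in the control to 13.88 with EGF and BCL6 from 12.66 to 7.68, while EGFR stayed between 14.40 and 15.31 in the 3 groups.

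Counts of list members below are over all genes tested, with those adjusted over the list alone in parentheses, and each list test is limma's camera with its adjusted p. Camera with an estimated correlation rests on 3 residual degrees of freedom, so it could hardly call a list. The FOXO list had an estimated correlation of −0.00183 for EGF against control, below the preset 0.01. Its unadjusted camera p-value still went from 6.38e-08 to 0.00983. The p-values with an estimated correlation thus do not show that correlation between genes explains the list calls. Delayed early and secondary EGF response genes had 12 members that rose and 1 that fell of 20 measured (13 and 1 adjusted over the list alone), with a camera adjusted p = 2.7e-08 and an adjusted p = 0.119 with an estimated correlation. Among them were PHLDA2 (3.58 ± 0.21), PLAUR, the urokinase receptor (2.95 ± 0.24), and PLAU, urokinase itself (2.17 ± 0.18). Of 23 feedback inhibitors of EGFR and MAPK signalling, 11 rose and 2 fell (13 and 3), with adjusted p = 3.29e-06, and adjusted p = 0.119 with an estimated correlation. The phosphatase DUSP4 rose by 2.92 ± 0.25 and CISH, another cytokine signalling inhibitor, by 3.28 ± 0.29 (at least 1.94-fold, within the negative-control range in the control). NF-kB and inflammatory cytokine targets had 11 of 21 members higher and 1 lower (14 and 1), with adjusted p = 1.41e-06, and adjusted p = 0.119 with an estimated correlation. TNFAIP3, a negative regulator of NF-kB, rose by 3.14 ± 0.18 and the cytokine IL1A by 3.09 ± 0.22, while TNFAIP2 fell by 1.61 ± 0.19. Of 20 interferon stimulated genes 11 rose and 1 fell (12 and 2), among them the antiviral genes OAS2 (1.96 ± 0.22) and MX1 (1.91 ± 0.20) and the transcription factor IRF1 (2.04 ± 0.18), with adjusted p = 5.19e-07, and adjusted p = 0.228 with an estimated correlation. Of 16 ribosome biogenesis and MYC targets 9 rose and 0 fell (10 and 0), with adjusted p = 5.19e-07, and adjusted p = 0.119 with an estimated correlation. NOP16 rose by 2.24 ± 0.19 and POLR1A, the large subunit of RNA polymerase I, by 1.49 ± 0.17. Without control 1, control 2, EGF 1 or EGF 2 in turn, the members called higher over all genes numbered 10 for the delayed early list, 8 for feedback inhibitors, 4 to 6 for NF-kB targets, 8 for interferon stimulated genes and 3 to 5 for ribosome biogenesis.

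Smaller shifts upward were found for 4 more lists. SRF and MRTF cytoskeletal targets had 6 of 18 members higher and 2 lower (9 and 2), with adjusted p = 0.000375, and adjusted p = 0.189 with an estimated correlation. The actin-binding protein TAGLN rose by 2.66 ± 0.18 (at least 4.34-fold). Of 14 heat shock proteins 6 rose and 0 fell (6 and 0), among them the chaperones HSPH1 (1.75 ± 0.17) and HSPA1A (1.51 ± 0.17), with adjusted p = 0.000746, and adjusted p = 0.146 with an estimated correlation. Cholesterol synthesis and SREBP2 targets had 5 of 15 members higher and 0 lower (6 and 0), with adjusted p = 0.000114, and adjusted p = 0.21 with an estimated correlation. HMGCS1, which makes HMG-CoA, rose by 1.17 ± 0.21 and was not called without control 1, control 2, EGF 1 or EGF 2 in turn (1.06 to 1.28). Hypoxia and glycolysis genes had 5 of 17 members higher and 0 lower (6 and 0), with adjusted p = 0.000115, and adjusted p = 0.21 with an estimated correlation. The hexokinase HK2 rose by 2.50 ± 0.32 (at least 4.56-fold) and the prolyl hydroxylase EGLN3 by 2.59 ± 0.30 (at least 1.34-fold). These counts rested on all the arrays compared. Without control 1, control 2, EGF 1 or EGF 2 in turn, limma called 1 SRF and MRTF target higher and 0 to 1 lower, 2 heat shock proteins higher, 0 cholesterol genes (5 to 6 higher at an unadjusted p under 0.05) and 2 to 3 hypoxia genes higher.

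Lists that shifted downward were led by FOXO and starvation induced genes, of which 11 of 19 fell and 1 rose (11 and 1). The camera adjusted p = 5.19e-07 for this list, and the adjusted p = 0.119 with an estimated correlation. Beside BCL6 and TXNIP, FBXO32, a ubiquitin ligase of muscle atrophy, fell by 3.25 ± 0.18 and GABARAPL1, an autophagy protein, by 2.40 ± 0.21. Of 7 AHR targets 4 fell and 0 rose (5 and 0), with adjusted p = 0.000115, and adjusted p = 0.119 with an estimated correlation. CYP1A1, the classical AHR target, fell by 3.17 ± 0.26 (at least 5.01-fold). BMP and TGF-beta targets had 6 of 18 members lower and 1 higher (6 and 1), with adjusted p = 0.0319, and adjusted p = 0.21 with an estimated correlation. ID3 fell by 3.06 ± 0.21 while INHBA, a subunit of activin, rose by 3.03 ± 0.17 (at least 5.15-fold), and the call of this list was lost without EGF 2 (adjusted p = 0.0658). Of 28 replication dependent histones 1 fell and 0 rose (6 and 0), with adjusted p = 0.00031, and adjusted p = 0.511 with an estimated correlation. That member was H4C5 (−1.06 ± 0.20), which was not called without control 1, control 2, EGF 1 or EGF 2 in turn, when limma called 0 histones (5 to 7 lower at an unadjusted p under 0.05), while 4 were called lower without EGF plus gefitinib 1 or 2. Without control 1, control 2, EGF 1 or EGF 2 in turn, the members called lower numbered 8 to 10 for the FOXO list, 3 for AHR targets and 4 to 5 for BMP and TGF-beta targets.

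The immediate early transcription factors were not called as a list (adjusted p = 0.0617), with 7 of 25 members higher and 3 lower (9 and 3). KLF6 rose by 2.17 ± 0.20, BHLHE40 by 1.63 ± 0.17 and MYC by 1.52 ± 0.17, and ELF3, an epithelial transcription factor, fell by 2.16 ± 0.25. The EGF family ligands and receptors (adjusted p = 0.0741) had 4 of 13 members higher and 1 lower (4 and 1). The ligands EREG (3.26 ± 0.18, at least 3.73-fold) and HBEGF (2.39 ± 0.17, at least 3.51-fold) rose and the receptor ERBB3 fell by 2.42 ± 0.18. YAP and TEAD targets had 4 of 13 higher and 2 lower (4 and 2), with adjusted p = 0.0736. The integrated stress response had 3 of 17 higher and 6 lower (4 and 9), with adjusted p = 0.109. p53 targets had 4 of 18 higher and 2 lower (7 and 3), with adjusted p = 0.173. G1 and S phase genes had 1 of 21 higher and 4 lower (4 and 5), with adjusted p = 0.515, and G2 and M phase genes 0 of 19 higher and 2 lower (0 and 2), with adjusted p = 0.103. mRNA decay factors had 3 of 10 higher and 1 lower (3 and 2), with adjusted p = 0.612, and the Notch pathway 1 of 15 higher and 1 lower (1 and 1), with adjusted p = 0.22. None of 12 cytosolic ribosomal proteins was called at adjusted p under 0.05, over all genes or over the list alone, and their list test gave adjusted p = 0.515. The median of the mRNA decay list was just under 0 while its mean was 0.28 and its test pointed up. Without control 1, control 2, EGF 1 or EGF 2 in turn, the members called fell to 4 to 5 higher and 1 to 2 lower for the immediate early list, 1 higher and 1 to 3 lower for the integrated stress response, 2 higher and 1 to 2 lower for p53 targets and 1 to 2 higher for mRNA decay factors. They were then 2 to 4 higher for the EGF family, 3 higher and 0 to 1 lower for YAP and TEAD targets and 1 lower each for G2 and M phase genes and the Notch pathway. limma called 0 G1 and S phase genes in these fits (3 to 5 higher and 5 to 6 lower at an unadjusted p under 0.05), and 3 higher and 4 lower without EGF plus gefitinib 1 or 2.

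Epidermal keratinocyte markers had 5 of 22 members higher and 6 lower (7 and 6), with adjusted p = 0.469, and 1 to 3 higher and 1 to 2 lower without control 1, control 2, EGF 1 or EGF 2 in turn. KRT10, a keratin of differentiating layers, fell by 2.77 ± 0.17. Markers of other cell types were also tested for changes between the groups, which cannot show a mixed culture that all groups share. Of 11 fibroblast markers 0 rose and 2 fell (0 and 2), with adjusted p = 0.184. These were LUM (−1.34 ± 0.26), not called without control 1, control 2, EGF 1 or EGF 2 in turn (−1.56 to −1.12), and DCN, which lay within the negative-control range in both groups (−1.21 ± 0.19) and was not called without control 2 (−1.11) or EGF 2 (−1.09). Of 14 leukocyte markers 1 rose and 0 fell (1 and 0), with adjusted p = 0.955. It was LCP1, an actin-bundling protein that carcinoma lines can also express (1.43 ± 0.20), not called without EGF 2 (1.36). Of 10 endothelial markers 0 rose and 1 fell (0 and 1), with adjusted p = 0.643. It was CDH5, a cadherin, at −2.22 ± 0.24, too dim for a fold. The leukocyte list had a median of −0.06, a mean of 0.02 and a test that pointed down, and the endothelial list a median of 0.06, a mean of −0.19 and a test that pointed down.

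In all, limma called 2554 probe sets for EGF against control at an adjusted p under 0.05, 1417 higher and 1137 lower, which stand for 2265 named genes. Of these probe sets 1564 changed at least 2-fold. At an unadjusted p under 0.05 there were 5677. Camera called 13 of 27 lists, and 0 with an estimated correlation, where 7 of the 27 had an unadjusted p under 0.05, and fry, which asks whether a list moves on balance one way, called 20. The count was 828 without control 1, 839 without control 2, 726 without EGF 1 and 736 without EGF 2.

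**Figure D2:**
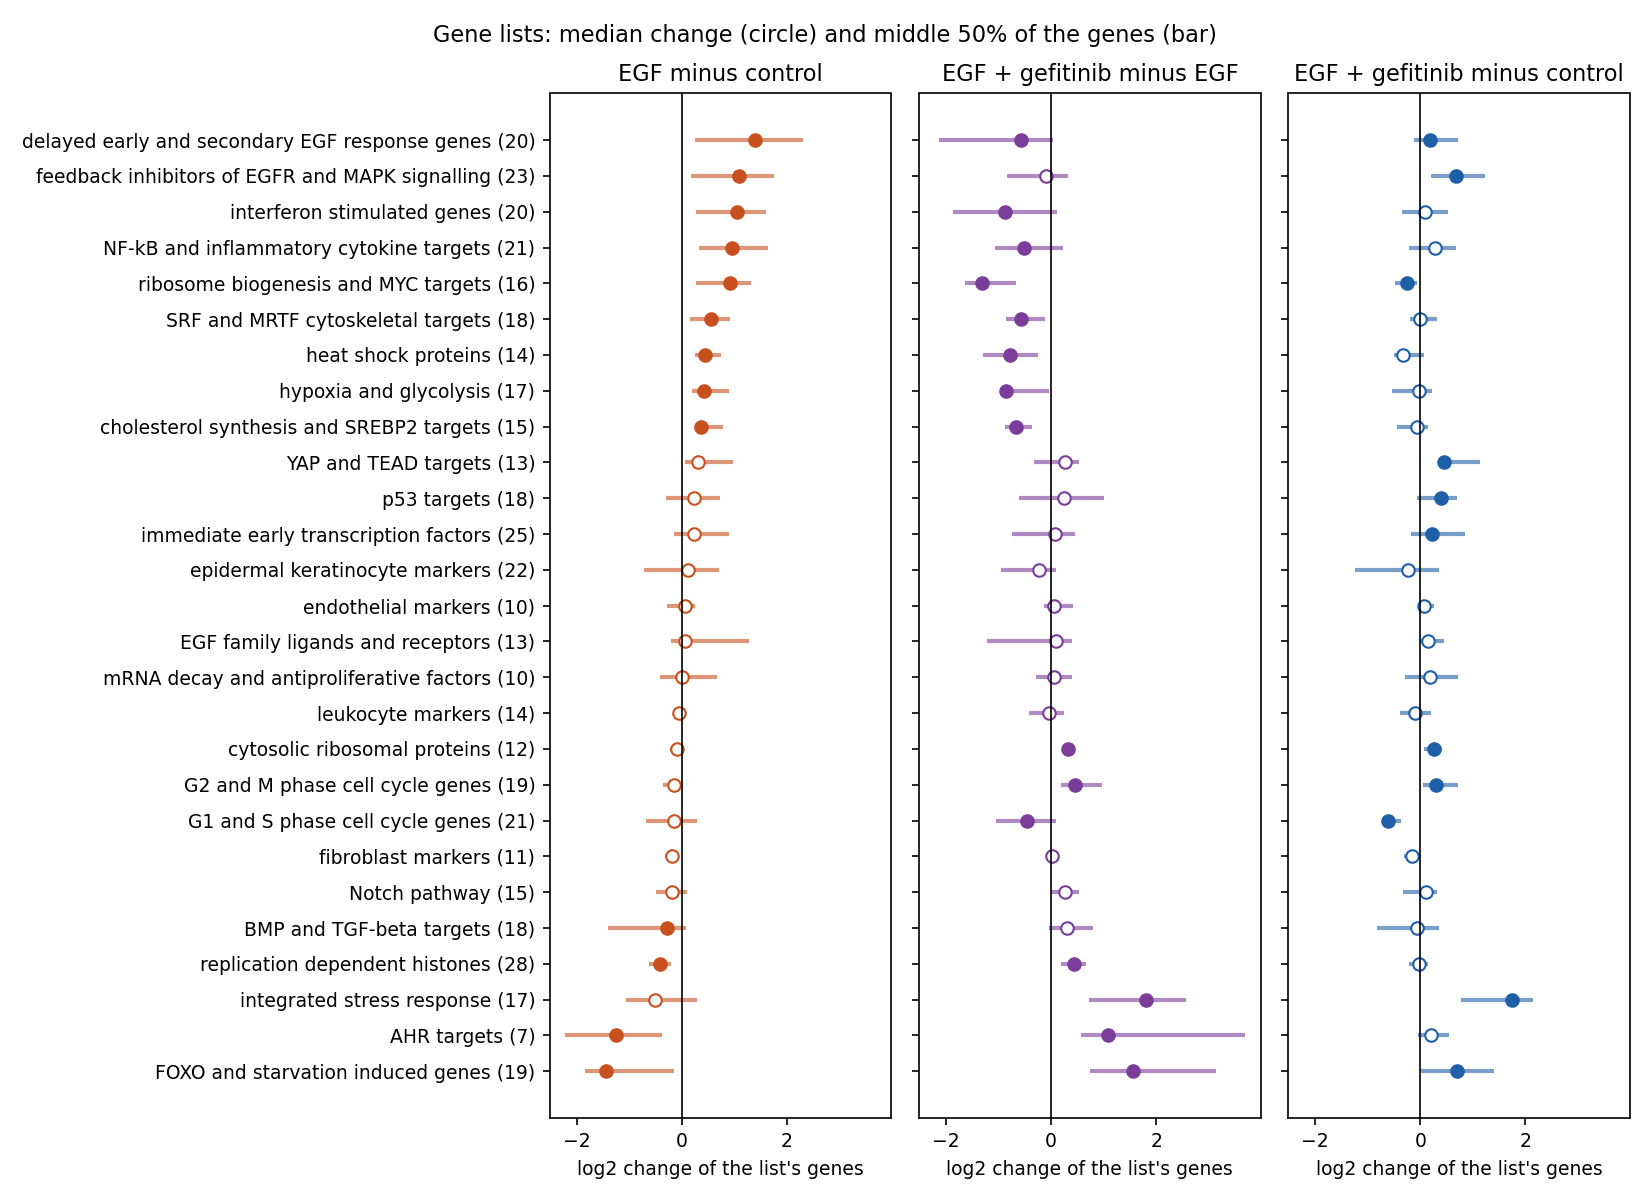
Median log2 change of the measured members of each of 27 gene lists (horizontal axis, circles) in the 3 comparisons, with a bar over the middle 50% of members; filled circles mark lists with a camera adjusted p under 0.05. The integrated stress response list had medians of −0.52 for EGF against control, 1.81 for EGF plus gefitinib against EGF and 1.75 for EGF plus gefitinib against control.

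The second comparison asked what gefitinib changed in the presence of EGF. Many of the genes that EGF had raised were lower. SOCS2 was at least 4.83-fold lower than with EGF alone, IL1RL1 at least 7.91-fold and FOSL1 15.9-fold. GJB2 and GJB6, gap junction proteins of the epidermis, fell 49.0-fold and 38.9-fold. With EGF plus gefitinib GJB6 measured 7.40, between the negative-control limits of the 2 arrays (7.65 and 7.29), so the size of its fall is uncertain. Genes that EGF had lowered were higher with gefitinib, among them CYP1B1 (at least 22.5-fold), TXNIP (at least 16.2-fold) and BCL6 (34.1-fold). CYP1A1 rose at least 36.1-fold and NUPR1, a stress-induced chromatin protein, 34.2-fold.

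In log2 units, CYP1B1 rose by 6.35 ± 0.19 (adjusted p = 3.52e-05), CYP1A1 by 6.03 ± 0.26 (adjusted p = 6.78e-05), TXNIP by 5.60 ± 0.18 (adjusted p = 3.52e-05) and FBXO32 by 4.61 ± 0.18 (adjusted p = 6.01e-05). SLC7A11, the cystine transporter, rose by 4.05 ± 0.42 (adjusted p = 0.00124). FAXDC2 (5.22), LMO4 and TCP11L2 (4.21 each), HBP1, a repressor of cell cycle entry (3.81), and MPPED2 (3.76) completed the largest rises. GJB2 fell by 5.62 ± 0.17 and GJB6 by 5.28 ± 0.17 (adjusted p = 3.52e-05 for each). CXCL10 (−5.54), HAS2 (−5.22) and IL7R (−4.50) fell, as did TIGAR, a regulator of glycolysis (−4.62 ± 0.46, adjusted p = 0.00111). The paralogs SERPINB3 and SERPINB4 fell by 7.10 ± 0.25 and 7.03 ± 0.24, and SPRR2A and SPRR2D by 5.05 and 5.04, with the split within each pair uncertain. Within the negative-control range in the dimmer group, beside CYP1B1, CYP1A1 and TXNIP, lay FAXDC2 (at least 19.97-fold), SLC7A11 (at least 10.8-fold), CXCL10 (at least 7.05-fold), HAS2 (at least 2.18-fold), IL7R (at least 5.97-fold), TIGAR (at least 2.50-fold), SERPINB3 and SERPINB4 (at least 37.6-fold and 36.4-fold) and SPRR2A and SPRR2D (at least 7.24-fold and 7.42-fold), so the order of these changes by size is not known. DUSP6 was 2.70-fold lower than with EGF alone, at 11.07 ± 0.23 (SD, n = 2). EGR1 fell by 2.12 ± 0.34 (adjusted p = 0.0061), to 9.66 ± 0.80 (SD, n = 2). EGFR was 1.82-fold higher, at 15.31 ± 0.07 (SD, n = 2, adjusted p = 0.0125), with a difference of 0.87 ± 0.17 that was not called without EGF 1 (0.86), EGF 2 (0.87) or EGF plus gefitinib 2 (0.81). FOS, within the negative-control range in both groups, differed by 0.88 (adjusted p = 0.0412), and this call was lost with quantile normalization, with median centring and without each of the 6 arrays in turn (0.63 to 1.14).

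FOXO and starvation induced genes had 15 of 19 members higher and 0 lower (15 and 0 adjusted over the list alone), with a camera adjusted p = 6.09e-11, and adjusted p = 0.0967 with an estimated correlation. CITED2 rose by 2.90 ± 0.19. The integrated stress response, the set of genes induced through ATF4, had 14 of 17 members higher and 0 lower (15 and 1), with adjusted p = 2.71e-10, and adjusted p = 0.145 with an estimated correlation. Asparagine synthetase ASNS rose by 2.56 ± 0.19, PPP1R15A, which restores translation after stress, by 2.15 ± 0.19 and CTH, of cysteine synthesis, by 2.77 ± 0.21 (at least 3.36-fold). Of 7 AHR targets 4 rose and 0 fell (4 and 0), with adjusted p = 5.63e-05, and adjusted p = 0.138 with an estimated correlation. G2 and M phase genes had 6 of 19 members higher and 0 lower (9 and 0), with adjusted p = 0.000116, and adjusted p = 0.138 with an estimated correlation. Of these CENPF, a kinetochore protein, rose by 1.94 ± 0.21 and TOP2A by 1.44 ± 0.20. Of 28 histones 5 rose and 0 fell (5 and 0), with adjusted p = 0.00303, and adjusted p = 0.589 with an estimated correlation. This list was not called without EGF plus gefitinib 1 (adjusted p = 0.132), and its members called higher numbered 0 without EGF 1 or EGF plus gefitinib 1 (limma, 6 and 4 at an unadjusted p under 0.05), 1 without EGF 2, 2 without control 1 or control 2 and 8 without EGF plus gefitinib 2. Without single arrays of the groups compared, 12 to 13 FOXO and 12 to 13 stress response members, 4 AHR targets and 4 to 7 G2 and M phase genes were called higher, with 4 of the last without EGF 1. The list of cytosolic ribosomal proteins was called upward (adjusted p = 0.0179, and adjusted p = 0.543 with an estimated correlation) though 0 of its 12 members passed limma's threshold, over all genes or over the list alone. Its call was lost without EGF 1 (adjusted p = 0.0789) or EGF plus gefitinib 1 (adjusted p = 0.0815).

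Ribosome biogenesis and MYC targets had 12 of 16 members lower and 0 higher (13 and 0), with adjusted p = 8.11e-09, and adjusted p = 0.0967 with an estimated correlation. NOP16 fell by 2.34 ± 0.19 and WDR12 by 1.81 ± 0.20. Delayed early and secondary EGF response genes had 8 of 20 members lower and 0 higher (12 and 0), with adjusted p = 5.63e-05, and adjusted p = 0.145 with an estimated correlation. PHLDA2 fell by 3.69 ± 0.21 and SPHK1, a sphingosine kinase, by 2.95 ± 0.29 (at least 4.43-fold). Of 15 cholesterol synthesis genes 9 fell and 0 rose (10 and 0), with adjusted p = 5.63e-05, and adjusted p = 0.194 with an estimated correlation. HMGCS1 fell by 2.14 ± 0.21 and ACAT2 by 1.63 ± 0.18. Hypoxia and glycolysis genes had 11 of 17 lower and 1 higher (12 and 2), with adjusted p = 0.000224, and adjusted p = 0.194 with an estimated correlation. PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by 2.56 ± 0.20. Of 14 heat shock proteins 9 fell and 1 rose (10 and 1), with adjusted p = 0.000442, and adjusted p = 0.145 with an estimated correlation. HSPA1A fell by 2.27 ± 0.17, and the member that rose was HSPB8, a small heat shock protein (2.63 ± 0.21). Without EGF 1, EGF 2, EGF plus gefitinib 1 or EGF plus gefitinib 2, the members called lower numbered 9, 8, 9 and 11 for ribosome biogenesis, 3, 3, 3 and 5 for cholesterol synthesis, 5, 4, 7 and 9 for hypoxia and glycolysis and 5, 4, 5 and 6 for heat shock proteins, and 7 for the delayed early list in each fit.

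Interferon stimulated genes had 10 of 20 members lower and 2 higher (10 and 2), with adjusted p = 0.000164, and adjusted p = 0.327 with an estimated correlation. MX1 fell by 2.78 ± 0.20. NF-kB targets had 6 of 21 lower and 0 higher (9 and 0), with adjusted p = 0.00303, and adjusted p = 0.194 with an estimated correlation. The cytokine IL1B fell by 3.78 ± 0.29. SRF and MRTF targets had 8 of 18 lower and 2 higher (11 and 2), with adjusted p = 0.00512, and adjusted p = 0.207 with an estimated correlation. TAGLN fell by 2.23 ± 0.18 (at least 3.83-fold) and cytoplasmic actin ACTB by 1.22 ± 0.19. G1 and S phase genes had 7 of 21 lower and 1 higher (9 and 1), with adjusted p = 0.0051, and adjusted p = 0.194 with an estimated correlation. RRM2, a ribonucleotide reductase subunit, fell by 1.81 ± 0.18. Without EGF 1, EGF 2, EGF plus gefitinib 1 or EGF plus gefitinib 2, the members called lower numbered 3, 3, 4 and 5 for SRF and MRTF targets, 5, 2, 5 and 8 for G1 and S phase genes and 5, 6, 5 and 6 for NF-kB targets, and 10 for interferon stimulated genes in each fit. Those called for the immediate early list were then 2 to 3 higher and 2 to 6 lower, for feedback inhibitors 2 to 4 higher and 5 lower and for keratinocyte markers 1 to 3 higher and 4 to 6 lower. Immediate early transcription factors had 4 of 25 higher and 4 lower (6 and 8, camera adjusted p = 0.854), with ATF3 up by 1.92 ± 0.20 (at least 1.60-fold) and EGR3 at −2.33 ± 0.27, too dim for a fold. Feedback inhibitors had 5 of 23 higher and 6 lower (5 and 8, adjusted p = 0.382), with DUSP10 up by 1.84 ± 0.18 and CISH down, at −3.28 ± 0.29 (at least 1.71-fold). Keratinocyte markers had 3 of 22 higher and 6 lower (3 and 7, adjusted p = 0.0544). Fibroblast markers had 0 of 11 called, leukocyte markers 1 of 14 lower (LCP1, −2.24 ± 0.20) and endothelial markers 1 of 10 higher (CDH5, 2.57 ± 0.24, at least 1.16-fold), the same counts as when adjusted over the list alone, with list tests at adjusted p = 0.838, 0.616 and 0.428. The EGF family list had a median of 0.09, a mean of −0.20 and a test that pointed down (adjusted p = 0.609), with 2 of 13 members higher and 4 lower (2 and 4). The lists of BMP and TGF-beta targets (limma camera, adjusted p = 0.0721), the Notch pathway (0.104), p53 targets (0.428), YAP and TEAD targets (0.609) and mRNA decay factors (0.818) were not called.

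limma called 4005 probe sets between EGF plus gefitinib and EGF, 1900 higher and 2105 lower, standing for 3467 named genes, and 2368 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 6732. Camera called 15 of 27 lists, and 0 with an estimated correlation, where 7 of the 27 had an unadjusted p under 0.05, and fry called 17. The count of probe sets was 1918 without EGF 1, 1889 without EGF 2 and 2572 without EGF plus gefitinib 2.

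Most changes made by EGF were turned back in this comparison. Of the 1417 probe sets raised by EGF, 1051 (74.2%) were called lower with gefitinib than with EGF alone, and 11 were called higher still. Of the 1137 lowered by EGF, 719 (63.2%) were called higher and 2 lower still. The 1770 opposite calls were set against 139 and 101 expected from independent lists of these sizes for the 2 directions. Both comparisons use the EGF arrays, and simulated unchanged groups sharing those arrays gave a correlation of −0.499, against −0.748 observed. The covariance was −0.313 against −0.0387 in the simulation, a difference of −0.274. With 1 EGF array in one comparison and the other EGF array in the other, the covariance was −0.278, against 0.000209 ± 0.00109 (SD) in the simulation. limma then called 510 and 506 probe sets in opposite directions for both ways to split the EGF arrays, of 736 and 1918 called in the single comparisons and of 726 and 1889. Independent lists would give 19.2 and 13.95 for the 2 directions the first way and 18.4 and 13.8 the other way. The estimate of the spread was still shared in part. The 1770 opposite calls became 670 without control 1, 666 without control 2, 553 without EGF 1 and 570 without EGF 2.

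**Figure D3:**
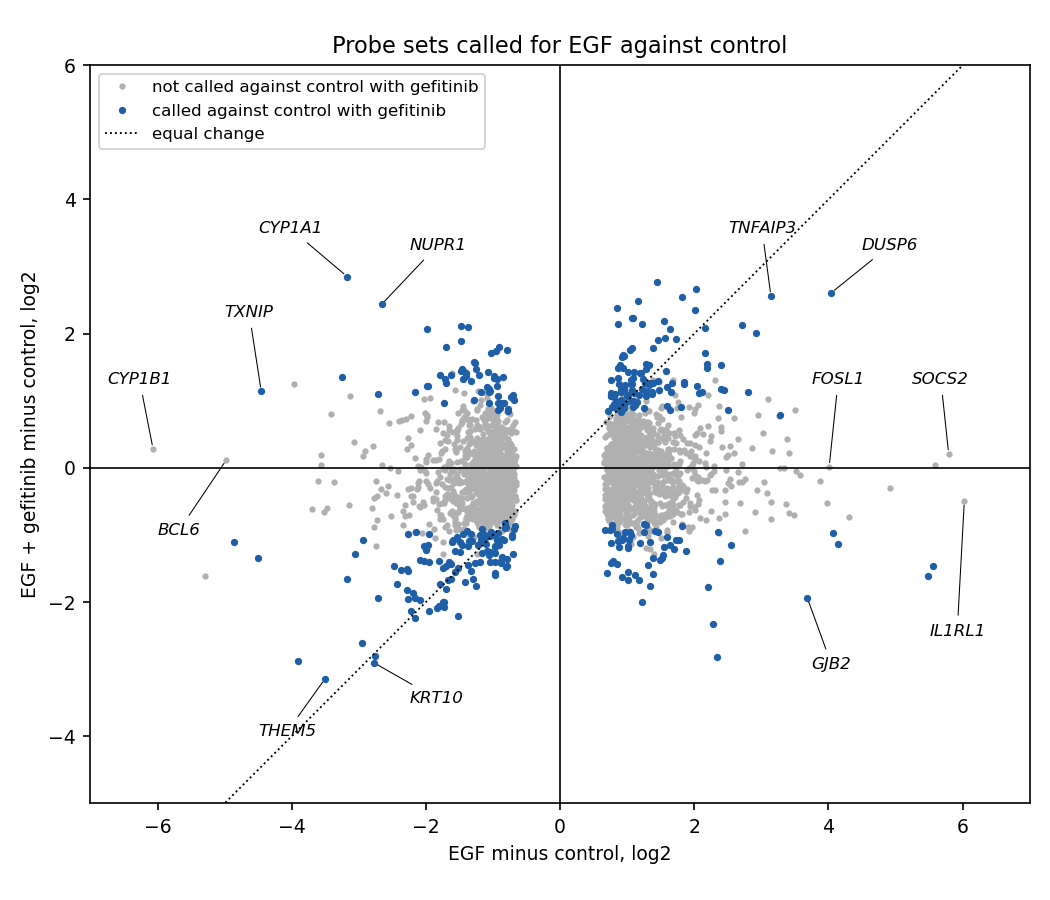
Log2 change of EGF plus gefitinib against control (vertical axis) plotted on the log2 change of EGF against control (horizontal axis) for the 2554 probe sets called for EGF against control, with those also called for EGF plus gefitinib against control in blue. Of the 1417 raised by EGF, 111 were still called above control with gefitinib and 59 were called below it.

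The third comparison set EGF plus gefitinib against the untreated control. It holds together what EGF still changed and what gefitinib itself changed, since a group given gefitinib alone was not analysed here. FNIP2, a folliculin partner in nutrient sensing, rose at least 5.95-fold, CHAC1, a glutathione-degrading enzyme of the stress response, at least 4.42-fold, and CYP1A1 7.22-fold. JUN, an AP-1 subunit, rose 5.85-fold, DUSP6 6.10-fold and TNFAIP3 5.91-fold. KRT10 fell 7.50-fold and THEM5, a mitochondrial thioesterase, 8.85-fold.

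FNIP2 rose by 3.94 ± 0.27 (adjusted p = 0.00618), CYP1A1 by 2.85 ± 0.26 (adjusted p = 0.00731), F2R, a thrombin receptor, by 2.82 ± 0.24 (adjusted p = 0.0069), CHAC1 by 2.79 ± 0.35 (adjusted p = 0.0153) and DDIT3, a transcription factor of the stress response, by 2.52 ± 0.27 (adjusted p = 0.0103). RNASE7, an antimicrobial ribonuclease (2.77), NABP1 (2.67), HSPB8 (2.51 ± 0.21) and AHNAK2 (2.50 ± 0.19) completed the largest rises. THEM5 fell by 3.15 ± 0.32 (adjusted p = 0.00915) and KRT10 fell by 2.91 ± 0.17 (adjusted p = 0.00618). SCNN1G (−2.88), RPTN, an epidermal matrix protein (−2.61), GRHL3, a transcription factor of the skin barrier (−2.35), MLLT11 (−2.33), RAB15 (−2.20) and WNT4 (−2.14) were lower. GPR15LG (−2.81), TIGAR (−2.33), CYP24A1 (−2.23) and TRIM31 (−2.14) were called lower at levels too dim for a fold. Of the others, F2R (at least 1.45-fold), RNASE7 (at least 3.78-fold), DDIT3 (at least 1.37-fold), SCNN1G (at least 1.08-fold), RPTN (at least 1.40-fold), GRHL3 (at least 2.99-fold), FNIP2 and CHAC1 lay within the negative-control range in the dimmer group, so the order of these changes by size is not known. EGR1 was 4.07-fold lower than in the control (−2.02, adjusted p = 0.0291) and EGFR 1.87-fold higher (0.91, adjusted p = 0.0372). FOS differed by 0.46 (adjusted p = 0.325).

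The integrated stress response had 12 of 17 members higher and 0 lower (14 and 0 adjusted over the list alone), with a camera adjusted p = 9.65e-15, and adjusted p = 0.152 with an estimated correlation. TRIB3, a pseudokinase (2.19 ± 0.21), STC2 (2.14 ± 0.18), PPP1R15A (2.13 ± 0.19) and CEBPG (1.75 ± 0.18) rose. Feedback inhibitors of EGFR and MAPK signalling had 8 of 23 higher and 0 lower (13 and 0), with adjusted p = 2.11e-07, and adjusted p = 0.152 with an estimated correlation. The phosphatases DUSP1 (2.14 ± 0.25, at least 1.18-fold), DUSP4 (2.01 ± 0.25) and DUSP5 (1.55 ± 0.20) rose. FOXO and starvation induced genes had 9 of 19 higher and 0 lower (11 and 2), with adjusted p = 5.2e-06, and adjusted p = 0.152 with an estimated correlation. Among these, IRS2, an adaptor of the insulin receptor, rose by 1.80 ± 0.24 and DDIT4, an inhibitor of mTORC1, by 1.78 ± 0.18. YAP and TEAD targets had 3 of 13 higher and 0 lower (5 and 1), with adjusted p = 0.00175, and adjusted p = 0.172 with an estimated correlation. CCN1, a matrix protein, rose by 1.91 ± 0.19. G2 and M phase genes had 4 of 19 higher and 0 lower (5 and 0), with adjusted p = 0.0019, and adjusted p = 0.169 with an estimated correlation. G1 and S phase genes had 4 of 21 lower and 0 higher (12 and 0), with adjusted p = 5.2e-06, and adjusted p = 0.152 with an estimated correlation. The replication factor MCM6 fell by 1.66 ± 0.25 and RRM2 by 1.52 ± 0.18. Without control 1, control 2 or EGF plus gefitinib 2, limma called 0 members of each list in this paragraph (13 to 14 of the integrated stress response at an unadjusted p under 0.05, 10 to 12 feedback inhibitors, 10 FOXO genes and 5 to 8 YAP and TEAD targets higher). Without EGF plus gefitinib 1 it called 5, 2, 2 and 1 of these higher, and without EGF 1 or EGF 2 10, 6, 6 and 1. Of the cell cycle lists it called 0 to 1 members without each array in turn (5 to 6 higher and 8 to 12 lower at an unadjusted p under 0.05 for G2 and M phase and for G1 and S phase genes).

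Each of the other lists called in this comparison lost its call without 1 or more of the single arrays. For 2 of them this held also without EGF 1 or EGF 2, which are outside the comparison, so dependence on particular arrays is not shown. Immediate early transcription factors had 6 of 25 higher and 1 lower (9 and 2), with adjusted p = 0.0262, and adjusted p = 0.337 with an estimated correlation. KLF6 rose by 2.08 ± 0.20 and ATF3 by 1.76 ± 0.20 (at least 1.69-fold), and the list's call was lost without control 2 (adjusted p = 0.0905) or EGF plus gefitinib 1 (adjusted p = 0.222). Delayed early genes had 4 of 20 higher and 1 lower (5 and 2), with adjusted p = 0.049, and adjusted p = 0.337 with an estimated correlation. VEGFA, the vascular growth factor, rose by 2.35 ± 0.18 and PHLDA1 by 2.12 ± 0.25. p53 targets had 4 of 18 higher and 1 lower (4 and 1), with adjusted p = 0.0142, and adjusted p = 0.264 with an estimated correlation. The p53 target PMAIP1 rose by 1.58 ± 0.19, and the list's call was lost without control 2 (adjusted p = 0.0508) or EGF plus gefitinib 2 (adjusted p = 0.0657). Ribosome biogenesis genes had 1 of 16 lower and 0 higher (2 and 1), with adjusted p = 0.047, and adjusted p = 0.276 with an estimated correlation. This call was lost without control 1 (adjusted p = 0.0514), control 2 (adjusted p = 0.0996) or EGF plus gefitinib 2 (adjusted p = 0.0791). Of the 12 cytosolic ribosomal proteins 0 were called, over all genes or over the list alone, while their list had adjusted p = 0.047, and adjusted p = 0.507 with an estimated correlation. The calls of the delayed early list and of the ribosomal protein list were lost without control 1, control 2, EGF 1, EGF 2 or EGF plus gefitinib 1, with adjusted p from 0.0511 to 0.222 for the former and from 0.0511 to 0.181 for the latter. Of the members of these lists, limma called 0 without control 1, control 2 or EGF plus gefitinib 2 (7 to 9 immediate early genes, 5 to 6 delayed early genes and 4 to 6 p53 targets higher at an unadjusted p under 0.05). Without EGF 1, EGF 2 or EGF plus gefitinib 1 it called 3, 3 and 2 immediate early genes, 3 delayed early genes in each fit and 2, 2 and 0 p53 targets higher. Keratinocyte markers had 2 of 22 higher and 7 lower (5 and 10, adjusted p = 0.0969), and 0 to 1 were called without control 1, control 2 or EGF plus gefitinib 2 (limma, 8 to 10 lower at an unadjusted p under 0.05). Markers of fibroblasts, leukocytes and endothelium had 0 of 11, 14 and 10 members called, with list tests at adjusted p = 0.155, 0.395 and 0.472. Over the list alone 2 fibroblast markers were lower and 1 endothelial marker was higher. The other 12 lists were not called, with adjusted p from 0.0511 for the EGF family to 0.875 for histones.

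limma called 834 probe sets between EGF plus gefitinib and control, 470 higher and 364 lower, standing for 747 named genes, and 4457 had an unadjusted p under 0.05. Camera called 11 of 27 lists, and 0 with an estimated correlation, where 6 of the 27 had an unadjusted p under 0.05, and fry called 19. The count of 834 was not stable. It fell without each of the 6 arrays in turn, most without control 1 or EGF plus gefitinib 2. It also fell without EGF 1 or EGF 2, which are outside this comparison. An effect of particular arrays and an effect of fewer arrays could not be told apart. All 834 probe sets kept their direction in each of these fits. They were chosen on these same arrays, and leaving out EGF 1 or EGF 2 cannot change their differences, so this was largely fixed in advance. Of the genes named here, none was called without control 1 or EGF plus gefitinib 2, and TNFAIP3, RNASE7, RPTN, NABP1, KRT10, FNIP2 and GPR15LG were called without control 2.

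Of the 1417 probe sets raised by EGF, 111 were still called above control with gefitinib, 59 were called below it and 1247 were called on neither side. Of the 1137 lowered by EGF, 112 were still called below control, 57 above it and 968 on neither side. Among the 470 probe sets higher than control with EGF plus gefitinib, 302 had not been called for EGF alone, and among the 364 lower, 193 had not. Of 117 named genes that EGF raised at least 4-fold, 107 were called below the EGF level with gefitinib, 18 were still called above control and 10 below it. Independent lists would give 31.1 and 19.3 calls in the same direction, against 111 and 112 observed. In opposite directions they would give 24.0 and 24.9, against 59 and 57. This expectation takes every probe set as equally likely to be called. Only 38.4% to 42.1% of them lay above the negative-control limit on the single arrays, so it may be too low. An excess of calls in opposite directions is therefore not shown. EGF against control and EGF plus gefitinib against control share the control arrays, and their changes correlated at 0.160 across probe sets, against 0.50 for simulated unchanged groups. The covariance was 0.0448 against 0.0388 in the simulation, a difference of 0.00599. With 1 control array in each comparison the covariance was 0.00845, against 0.0000336 ± 0.00107 (SD) in the simulation, and the correlation 0.0267. The shared calls could not be counted in this way, because with 1 control array too few probe sets were called between EGF plus gefitinib and control. Part of the excess in the same direction may thus come from the shared arrays.

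To measure how much of the EGF change was left, probe sets were chosen on the arrays of 1 number and measured on those of the other. The 50 probe sets with the largest rise on arrays 1 rose by a median of 3.17 with EGF on arrays 2, and −4.83% of that rise was left with gefitinib. Chosen on arrays 2 and measured on arrays 1, the median rise was 3.20 and −6.70% was left. For the 50 largest falls, 11.4% and 0.402% were left. These shares use the values as measured and took no account of the negative-control limit. Some of the largest rises, such as that of SOCS2, started within the negative-control range and returned to it. Some of the largest falls, such as those of CYP1B1 and TXNIP, ended within it. For such genes neither the size of the change nor the share left is known exactly. Over the 25 immediate early transcription factors, of which 10 were called for EGF, the slope of the change with EGF plus gefitinib on the change with EGF was 45.6%, and the median share left over those 10 members was 52.0%. Both changes subtract the same control arrays, which alone can give a slope: 100 simulations of unchanged groups gave 50.6 ± 22.6% (SD). Those simulations held no EGF change, while in the data the mean product of the EGF changes on separate arrays was 1.01. The simulated slope is therefore not a reference for this list and does not decide whether a change was left. With each change taken on arrays of a different number, so that no control array entered both, the slope was 46.4%. The mean product of the changes was then 0.470, against 0.00301 ± 0.0253 (SD) and at most 0.0798 for the unchanged groups. A mean product is weighted toward members with large changes in both, such as KLF6 and JUN. JUN measured 10.2 on each array with EGF and 11.1 and 10.7 with EGF plus gefitinib, so its product is not a share left. The slope therefore does not describe the list as a whole. What was left can come from EGF or from gefitinib itself, and no test compared this slope with the share left of the 50 largest rises, which is another measure.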

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

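The tests of explanations given in this part were all chosen only after the results they bear on were seen.

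The positive-control probe sets, which take no part in the comparisons, carried signal that differed between groups. Of 2197, limma called 263 higher and 35 lower in the EGF group than in the control, 81 higher and 470 lower with EGF plus gefitinib than with EGF, and 3 higher and 34 lower with EGF plus gefitinib than in the control. Of 612 negative-control probe sets 23, 41 and 10 (3.76%, 6.70% and 1.63%) were called in these comparisons. The calls of transcript probe sets came to 11.9%, 18.7% and 3.89% of those tested, and the share of false calls among them was not measured. Of the 63 ERCC and 8 other spike probe sets 0 were called in any. The median of the ERCC probe sets was 4.32 to 4.47 on the arrays, below the negative-control limits of 7.14 to 7.65. Their lack of calls therefore does not show that spike signal was equal between groups.

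In the EGF group, late response genes had changed while EGR1 differed from control by 0.10 and FOS lay within the negative-control range, although the labels give 30 min, a time at which EGF is known to induce both. The median of the delayed early list was 1.16 log2 units above that of the immediate early list, but this restates the pattern, and 7 immediate early members rose and 3 fell, so it does not decide whether the arrays hold a first wave of transcription, which stays open. An exchange of single arrays between groups was argued against, since the lowest correlation within a group lay 0.00449 above the highest between groups. A harvest later than labelled had the values it needs: 69 called falls, measured only down to the negative-control limit, were larger than a half-life of 15 min allows in 30 min, and the fall of CYP1B1, at least 18.5-fold, would need a half-life of at most 7.13 min. A later harvest or a longer exposure to EGF may explain the profile as a hypothesis, but there was 1 time point, half-lives were not measured, and fast decay of these transcripts stays open.

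The integrated stress response list was higher with EGF plus gefitinib than in both other groups, with a median of 1.75 over control. It was called by camera in both comparisons (adjusted p = 2.71e-10 against EGF and 9.65e-15 against control) but not with an estimated correlation (adjusted p = 0.145 and 0.152). Array scaling or a shift that depends on level was argued against, since the highest median among 10000 random lists matched on mean level was 0.588. A single array was argued against as well, as the median was still 1.65 without EGF plus gefitinib 1 or 2, whichever gave less. An EGF response left in place by gefitinib would need a rise with EGF alone, where the list's median was −0.519. This holds for the list and not for each member: of the 12 members called over control, 2 had at least 50% of that change with EGF alone, TRIB3 (1.55 of 2.19, limma adjusted p = 0.00552 for EGF) and CEBPG (1.04 of 1.75, limma adjusted p = 0.0131), and for these an EGF response left in place stays open. An effect of gefitinib itself, or of the loss of EGFR signalling, may be the source, but it could not be tested, because no group had gefitinib alone.

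Some genes that EGF raised at least 4-fold stayed above control with gefitinib while others returned to it. Probe sets that kept at least 50% of the rise on the arrays of 1 number (14 and 22 of them) kept a median of 67.5% and 59.0% on the other arrays, which argues against measurement error around a full return. The rest (108 and 122) kept −9.29% and −9.26%, so that the sorted sets differed by at least 68.3 percentage points. The size of this difference is not known. Genes such as CXCL10 and HAS2 lay within the negative-control range both in the control and with gefitinib. FOSL1 and DUSP6 lay above that range in every group. With EGF plus gefitinib FOSL1 measured 10.2 and 9.55 on its 2 arrays, against 9.95 and 9.79 in the control. DUSP6 measured 11.2 and 10.9, against 8.36 and 8.56. For these 2 genes the values argue against the same share being left. The genes that stayed above control may depend less on the EGFR kinase or may respond to gefitinib itself, and with no group given gefitinib alone these could not be separated.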

How the results depend on the processing

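Array weights, keeping the control probe sets, centring for named genes and separate control or EGF arrays were chosen only after the results were seen, and the other alternatives before. No named gene called in the main fit reversed with quantile normalization, centring, a replicate block or without single arrays. No called list reversed with these (centring not tried), with the other list tests or above the median. Genes named for the largest changes had arrays that did not overlap between the groups, so leaving out 1 array could not reverse them. Calls were lost, however: without single arrays 2 to 31 of 108 named genes of the first comparison (25 to 31 without a control or EGF array), 4 to 14 of 110 of the second and 26 to 81 of 82 of the third, and 5, 4 and 19 with a replicate block. Of the called lists, 0 to 1 of 13, 0 to 2 of 15 and 2 to 5 of 11 lost their call without single arrays, and 0, 0 and 2 with the block. The other settings were not tried on single genes. The balance of the third comparison (470 higher, 364 lower) turned to 1372 and 1398 with an intensity trend and to 1183 and 1225 above the median. EGF against control (2554 calls) gave 4237 with an intensity trend, 3948 above the median value, 1361 with treat, 1690 at an unadjusted p with 2-fold change and 726 to 2506 without single arrays, the lowest without EGF 1. EGF plus gefitinib against EGF (4005) gave 2476 with treat, 2470 at an unadjusted p with 2-fold change and 1889 to 3406 without single arrays, the lowest without EGF 2. EGF plus gefitinib against control (834) gave 247 with the 4 arrays compared, 2770 with a trend, 1457 and 2408 above the 25th percentile and the median, 268 with treat, 1951 at an adjusted p under 0.1, and 0 to 247 without single arrays (limma, with 3280 and 3810 at an unadjusted p under 0.05 where 0 were called, without control 1 and without EGF plus gefitinib 2). treat lowers counts by its own construction. Fewer tests alone could give the filter at the median at most the counts at an adjusted p under 0.1 (3814 for EGF and 1951 for EGF plus gefitinib against control), and it gave more in both. For EGF plus gefitinib against EGF it gave 5049, which is below the 5506 at that threshold. For the filters and the rest the cause was not tested. Of the lists called by camera (13, 15 and 11), 0, 0 and 0 were called with an estimated correlation, while fry called 20 in the first comparison and 19 in the third. Without single arrays the third gave 6 to 9 lists, with 6 without control 2. The share left over the immediate early list (45.6%) was 52.0% as a median over called members, 53.1% over members above the median, 46.4% with separate control arrays and 41.1% to 50.04% without single arrays, the lowest without EGF plus gefitinib 1. Unchanged groups with shared controls gave 50.6%, but they held no EGF change, so this slope is not a reference for the share left. Of these values, the one with separate control arrays is free of the shared control arrays. That value is weighted toward members with large changes. The share left of the largest rises on split arrays (mean −5.76%) was −7.77% with 20 probe sets, and that of the largest falls (11.4% and 0.402%) was not repeated. None of the shares on split arrays took account of the negative-control limit. The 1770 opposite calls were 553 to 1428 without single arrays and 510 and 506 with separate EGF arrays, where each comparison had fewer arrays. Array weights gave 3118, 3729 and 612 calls, and keeping control probe sets 2417, 3912 and 564. Quantile normalization gave 2539, 3945 and 875, and centring 2586, 3981 and 844. Neither moved the share of higher calls by over 10 percentage points or the median of all probe sets by over 0.1. Signal over background limits the rest, since 38.4% to 42.1% of transcript probe sets lay above the negative-control limit.

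No pairing by replicate number was seen in the values: the deviations of same-numbered arrays correlated at −0.0410, 0.0213 and −0.00354. This does not show whether same-numbered samples were handled together, which the labels do not say. With the replicate number as a block the counts were 2040, 3489 and 333 and the opposite calls 1431.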

Other observations

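The genes named in this part were chosen after their values were seen, and no further tests of explanations were made. Some genes that interferon gamma is known to induce were raised by EGF, but no list of such genes was fixed or tested. The nearest list, interferon stimulated genes, was called for EGF by camera (adjusted p = 5.19e-07). It was not called with an estimated correlation (camera adjusted p = 0.228), a test on 3 residual degrees of freedom that could hardly call a list. CXCL9 (3.49 ± 0.45, limma adjusted p = 0.00463), CXCL11 (3.41 ± 0.28, limma adjusted p = 0.0012), the tryptophan-degrading enzyme IDO1 (3.52 ± 0.44, limma adjusted p = 0.00449) and the GTPases GBP1 (2.75 ± 0.24, limma adjusted p = 0.00134) and GBP5 (3.15 ± 0.30, limma adjusted p = 0.00168) rose with EGF. With EGF plus gefitinib CXCL9 lay −4.20, CXCL11 −3.19, IDO1 −3.57, GBP1 −3.70 and GBP5 −2.91 from the EGF level, all called. The hyaluronan synthase HAS3 rose by 3.36 ± 0.35 with EGF and differed by −3.91 from that level with gefitinib. All of these but GBP1 lay within the negative-control range in the control and with EGF plus gefitinib, so the log2 differences do not give sizes: the rises with EGF came to at least 1.65-fold for CXCL9, 6.65-fold for CXCL11, 2.83-fold for IDO1, 1.84-fold for GBP5 and 1.69-fold for HAS3, and the falls with gefitinib to at least 1.45-fold, 5.87-fold, 2.50-fold, 1.62-fold and 1.49-fold.

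A few genes of keratinocyte differentiation were low in both groups given EGF, but the epidermal keratinocyte list was not called: 5 members rose and 6 fell with EGF (camera adjusted p = 0.469), and 2 rose and 7 fell with EGF plus gefitinib against control (camera adjusted p = 0.0969). SPRR2A and SPRR2D rose with EGF (at least 8.21-fold and 8.41-fold), and the keratin KRT13 was not called for EGF (−0.59, limma adjusted p = 0.0846). The keratin KRT4 measured 16.25 in the control, 15.13 with EGF and 15.24 with EGF plus gefitinib, and both treated groups were called below control (limma adjusted p = 0.0124 and 0.0381) while they differed by 0.11 ± 0.19 from each other (limma adjusted p = 0.746). KRT10 differed by −2.77 and −2.91 from control, IVL, a cornified envelope precursor, by −1.73 and −2.01, and THEM5 by −3.50 and −3.15, with differences between the treated groups of −0.14, −0.28 and 0.36 that were not called. For EGF against control, the call of KRT4 was lost without control 1, EGF 1 or EGF 2 in turn (−1.24 to −0.99 without each of the 6 arrays) and that of IVL without control 2 (−1.64) or EGF 2 (−1.66), and IVL lay within the negative-control range in both treated groups. The gap junction genes went past control: GJB2 was 3.68 above control with EGF and −1.93 from it with EGF plus gefitinib, and GJB6 4.15 and −1.14. With EGF plus gefitinib GJB6 lay near the negative-control limit, at 7.40, so the size of its difference from control there is uncertain. FNIP2 and AHNAK2 were not called for EGF (0.31 and −0.50) and were 3.94 (at least 5.95-fold, within the negative-control range in the control) and 2.50 above control with gefitinib added. Each call against control with EGF plus gefitinib named here was lost without control 1 or EGF plus gefitinib 2, when limma called 0 probe sets (3280 and 3810 at an unadjusted p under 0.05), those of GJB2, IVL, THEM5 and AHNAK2 also without control 2, that of IVL also without EGF plus gefitinib 1, and those of KRT4 (−1.13 to −0.88) and GJB6 (−1.19 to −1.09) without each of the 6 arrays in turn.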
